A study of Bigelowiella natans with 9 samples.

How the data were processed

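Messenger RNA of Bigelowiella natans strain CCMP2755 was measured in 9 libraries, 3 each from cells kept for 4 h under very low light (VL, 20 µmol quanta per square metre per second), low light (LL, 60, the reference) or high light (HL, 400). Per the labels, the libraries were made with a stranded Illumina mRNA kit. Whether the authors' quantification used strand is not given in the sources used here, so reads of overlapping and antisense models cannot be separated. FastQC, TopHat2, Cufflinks 2.2.1 and Cuffdiff are named in the submitters' processing notes. The genome build and the annotation release are not given in the sources used here.

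The authors deposited one table of FPKM per library, with a value, a confidence interval and a quantification status for each gene model, per the file headers. The authors also deposited tables of log2 fold changes with p-values and q-values for the 3 pairs of light conditions, 1 for all 22202 loci per comparison and 1 for the 21559 loci with a protein ID. Each library table held 22320 entries, of which 3 had no ID and were left out, leaving 22317 gene models on 260 scaffolds. Models were joined by ID because their order differs between tables. Start coordinates are given 1-based, on the scaffolds named in the authors' tables.

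FPKM carries no read counts, so no count test was the main analysis. An estimate of depth was taken from the deposited interval, as the number of fragments whose counting error would give an upper bound 2 SD above the value. It gave 25.07 to 34.63 M fragments per library (M stands for mega), with models listed at 0 counted as 0. Between 70.3% and 73.8% of the models under 30 such fragments lay within 0.05 of a whole number, far more than evenly spread values would give. The rest did not, so whole counts were not recovered throughout and the numbers serve only as estimates. In the VL and LL libraries, up to 34 models had the status HIDATA, which Cufflinks gives to a locus with too many fragments, and were listed at 0. These zeros are failed estimates and no fold change is given for them.

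The test used log2(FPKM + 1) of models with a mean FPKM of at least 1 over the 9 libraries, which left 19601 models and took out 2716. One limma model (limma 3.58.1 in R 4.3.3) was fitted to all 9 libraries with a mean per light condition and a variance trend. Each pair of conditions was tested two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low models. The labels describe growth and sampling in triplicate but do not tie libraries to cultures, so the p-values measure the spread between these libraries only. The fit was tested for HL against LL on simulated data of 19601 models. Their spread was that within conditions over all 9 libraries, and libraries were drawn independently. It found 29.9%, 68.7% and 97% of models changed by 0.5, 1 and 2 on the log2 scale, with 6 false calls among 136.

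Only 25 gene models carried a symbol in the authors' tables, with 23 different symbols. None of the 22317 model IDs matched the 426 genes of the reference gene table (assembly ASM245v1), and 3 symbols occur in both in name only. Of the gene lists fixed beforehand, the photosystem and electron transport list had 1 member (PETC), the ribosomal protein list 1 (RPL3) and the other lists 0, so no list reached the 5 members required for a test. The lists matched words of product names, and abbreviated symbols such as ATUB-3, BTUB, HIS2B and PSMB matched none, so a 0 does not mean that no such gene was measured. Counted by meaning, the 3 tubulin models would have reached the 3 members needed for the naming rule; they are described among the models with a symbol. What a symbol stands for is read from general knowledge, since the tables do not spell it out. The rule for named genes took, per comparison, up to 10 models with a symbol in each direction, past the threshold, with a mean FPKM of at least 10 and no overlap between replicates. Members of lists with at least 3 tested genes were to be added, which named none. Among models without a symbol it took the 2 with the largest change in each direction. Where this picked models with a failed estimate, the next ones were taken instead, a change made after the values were seen. Other models with a symbol are given as a summary or as values, and any grouping of them was made after their names were seen. Models of the same family (ACT, BTUB, SNRNP) can share reads and are uncertain to that extent.

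Fixed before the data were examined were the groups, the test, the naming rule and the following alternatives: pseudocounts of 0.1 and 10, no filter and a filter at 5 FPKM, median-ratio scaling, quantile normalization, only models with status OK in all libraries, only the 6 libraries compared, no variance trend, a fold change of at least 2, the replicate number as a block, leaving out each library in turn, and the authors' q under 0.05. Alternatives chosen after seeing the data were the fits without the libraries numbered 1 limma's voom on the implied fragments, and, for the models with a symbol, the fit of only the 6 libraries compared and the fit without a variance trend, which had been planned for the counts. Whether equal replicate numbers pair libraries was checked by correlating deviations from the group means across models. All 3 same-numbered pairs of HL and LL were over 0.1 (0.19 to 0.41), so for HL against LL the numbers were taken to pair the libraries, a reading settled after the blocked fit had been seen. The main fit, fixed beforehand, has no block, so its p-values and counts for HL against LL do not use this pairing. The blocked fit covers all 9 libraries and so also blocks VL. For VL against LL and HL against VL, 2 of 3 pairs were over 0.1, so there the libraries were not treated as paired, which leaves open whether they are. Without the libraries numbered 1, the correlation for HL and LL was 0.055, so the pairing rests on those libraries. Among unequal numbers, LL replicate 2 with HL replicate 3 and LL replicate 3 with HL replicate 2 were also over 0.1, both at 0.16. Deviations within a group sum to 0, so the 3 same-numbered pairs are not separate evidence. Whether the HL and LL libraries are paired therefore stays open as well. The labels do not name a shared culture or day. Overlap between the comparisons against LL was set beside independent lists and 20 simulations of unchanged groups with independent libraries, and 20 with libraries of equal number correlated as observed, the latter added after the data had been seen. The covariance over models with status OK in all libraries, the position of LL between VL and HL, the correlation of neighbouring models and the checks of failed estimates, library numbering and depth were added after the data had been seen. The neighbour step, run on 19570 models of the HL vs LL comparison, recovered a simulated correlation of 0.3 as 0.297. Other splits of the 6 libraries of each comparison were counted, with the prediction written before their result was seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for joining and drawing.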

Results

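Transcript levels were measured in Bigelowiella natans, a unicellular marine alga of the chlorarachniophytes, whose plastid descends from an engulfed green alga that left a relict nucleus, the nucleomorph. Cells acclimated to low light (LL, 60 µmol quanta per square metre per second) either stayed there or were moved for 4 h to very low light (VL, 20) or high light (HL, 400), with 3 libraries per condition. The 3 comparisons ask which transcripts differ after a rise in light, after a fall in light, and between the extremes. FPKM summed to 645555 to 653874 in the VL libraries, 657210 to 668969 in LL and 722855 to 744507 in HL. The estimated depth was 25.51 to 29.0 M fragments in VL, 25.07 to 28.07 M in LL and 26.27 to 34.63 M in HL. Both sums leave out failed estimates, which are listed at 0. These fell on 6, 34 and 34 models in VL replicates 1 to 3, on 5, 33 and 16 in LL and on 0 in HL. The VL and LL sums are therefore understated by an unknown amount, and part of their difference from HL may come from this. Within a condition, log2(FPKM + 1) correlated across models at 0.966 to 0.991 in VL, 0.966 to 0.982 in LL and 0.964 to 0.988 in HL (models are not independent replicates). Of 22317 gene models, 25 carried a symbol, and these are described first in each comparison.

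After 4 h of high light, RPL3, a protein of the large ribosomal subunit, stood at 890 ± 293 FPKM (SD, n = 3) against 96.6 ± 25.3 in low light, 8.97-fold higher (log2 fold change 3.16, SE 0.33, limma adjusted p = 0.00023). Its model, estExt_Genewise1.C_430005, lies on scaffold 43 from 17578 to 19672. FBAIP rose 4.1-fold, from 1060 ± 272 to 4262 ± 494 FPKM (n = 3 each, limma adjusted p = 0.00144). ACT1, an actin, rose 3.09-fold, from 110 ± 15.2 to 344 ± 64.8 FPKM (n = 3 each, limma adjusted p = 0.00277). FBAII, a class II aldolase of sugar metabolism, rose 2-fold, from 55.9 ± 17.1 to 111 ± 17.3 FPKM (n = 3 each, limma adjusted p = 0.00655).

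Among the 25 models with a symbol, 12 were higher in HL than in LL, 4 were lower and 9 did not pass the threshold. EIF6, a translation initiation factor, was 1.88-fold higher and EIF-5A, another translation factor, 1.44-fold higher. PETC, the Rieske iron-sulfur protein of the cytochrome b6f complex of photosynthetic electron transport, rose 1.8-fold, from 936 ± 129 to 1675 ± 119 FPKM (n = 3 each, limma adjusted p = 0.00277). It was the only member of the fixed photosystem list, as RPL3 was of the ribosomal list, and both rose. GSP2, a Ran-type GTPase of nuclear transport, rose 1.67-fold, PSMB, a proteasome beta subunit, 1.4-fold, and GAPX 1.83-fold. SNRNP on scaffold 50, a small nuclear ribonucleoprotein component, was 1.32-fold higher, and ARF1, a GTPase of vesicle traffic, 1.29-fold higher. The 4 lower models were COFL, the actin-binding protein cofilin (723 ± 91.8 to 501 ± 131 FPKM, n = 3 each), BTUB starting at 78705 on scaffold 78, a beta tubulin (739 ± 61.2 to 585 ± 2.13 FPKM, n = 3 each), RJL, a Rab-like GTPase, and SNRNP on scaffold 6. Their reductions were between 1.18-fold and 1.47-fold. ACT2 stood at 4466 ± 761 FPKM in HL and 3646 ± 424 in LL, and ACT3 at 20.6 ± 4.88 and 21.1 ± 2.95, neither past the threshold (n = 3 each, limma adjusted p = 0.192 and 0.841). Whether ACT1 differs from ACT2 and ACT3 in its response was not tested. ATUB-3, an alpha tubulin, stood at 7.81 ± 0.84 FPKM in HL and 8.13 ± 3.3 in LL (n = 3 each, limma adjusted p = 0.982). With the replicate number as a block, 2 further models with a symbol passed the threshold, ACT2 (log2 fold change 0.29, limma adjusted p = 0.0362) and ARP (-0.28, limma adjusted p = 0.0408).

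RPL3, FBAIP, ACT1, FBAII, EIF6 and GSP2 passed the threshold in each of 21 alternative fits. GAPX lost its call without HL replicate 2 (limma adjusted p = 0.0507), PETC under quantile normalization (0.145), EIF-5A under quantile normalization (0.768) and without LL replicate 2 or 3, and ARF1 without any of 8 single libraries (up to 0.141, without LL replicate 3), its fold change turning negative under quantile normalization (log2 fold change -0.15). COFL, RJL, PSMB, BTUB and both SNRNP models each lost the call without 2 or more single libraries, with adjusted p values of up to 0.137, and median-ratio scaling ended the calls of COFL, RJL and SNRNP on scaffold 6. Quantile normalization also ended the calls of PSMB and SNRNP on scaffold 50. The fit with voom ended those of ARF1 and SNRNP on scaffold 50. Fitting only the 6 HL and LL libraries, tried on these models after the data had been seen, ended the calls of ARF1 (adjusted p = 0.0954), COFL (0.0732), SNRNP on scaffold 6 (0.0666) and scaffold 50 (0.0645), RJL (0.057) and BTUB (0.0527).

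**Figure D1:**
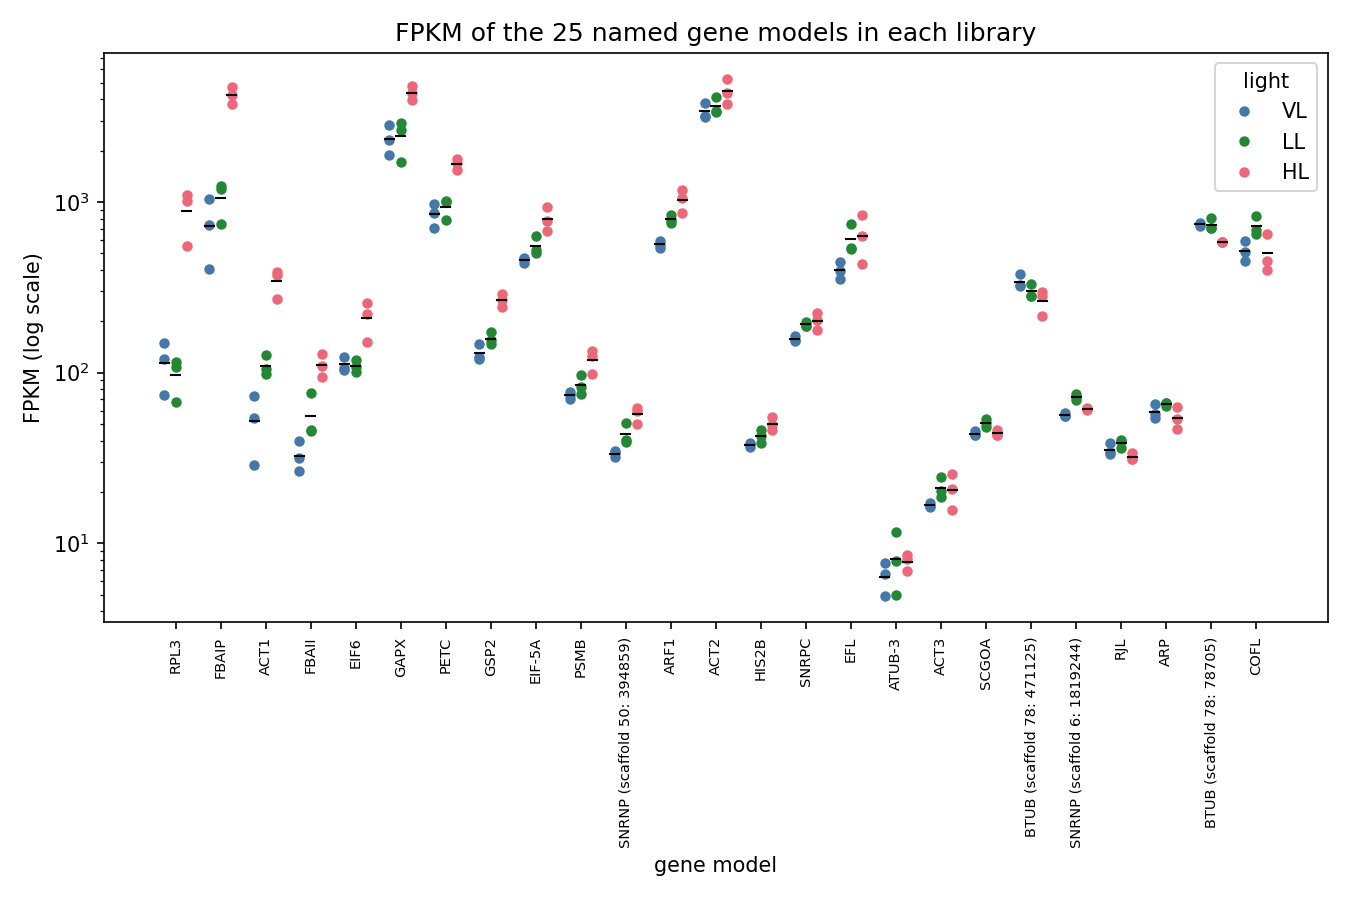
FPKM (log scale) of the 25 gene models with a symbol in each of the 9 libraries; dots are libraries coloured by light condition, black bars are means of 3, and models run from the largest increase to the largest decrease in HL against LL. RPL3 averaged 890 FPKM in HL against 96.6 in LL, and COFL 501 against 723.

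Across all 19601 models tested, 3375 were higher and 3887 lower in HL than in LL, 37% of the total. At a fold change of at least 2, 1063 were higher and 697 lower. With the replicate number as a block and no cut on fold change, 4051 were higher and 4924 lower. The replicates of HL and LL did not overlap for 9628 models (49.1%), where chance gives 10%. The naming rule took models past the threshold, with a mean FPKM of at least 10 over the 9 libraries and no overlap between replicates. Among such models without a symbol and quantified in all libraries, the largest rises were in estExt_Genewise1Plus.C_990022 (scaffold 99, 147036 to 147900), from 34.4 ± 8.14 to 450 ± 187 FPKM, and estExt_Genewise1Plus.C_140009 (scaffold 14, 79071 to 82581), from 8.12 ± 3.79 to 97.1 ± 50.7 (n = 3 each). The largest falls were in estExt_fgenesh1_pm.C_110014 (scaffold 11, 670050 to 671100), from 1071 ± 424 to 71.1 ± 4.51 FPKM, and fgenesh1_pm.33__7 (scaffold 33, 273379 to 279088), from 18.4 ± 0.673 to 1.7 ± 0.905 (n = 3 each). Of the calls, 46.5% were increases, against 52.5% after median-ratio scaling, which turned the balance, and 31.4% when the implied fragments were tested with voom, a fit chosen after seeing the data in which the median model moved by -0.17 on the log2 scale against -0.046.

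**Figure D2:**
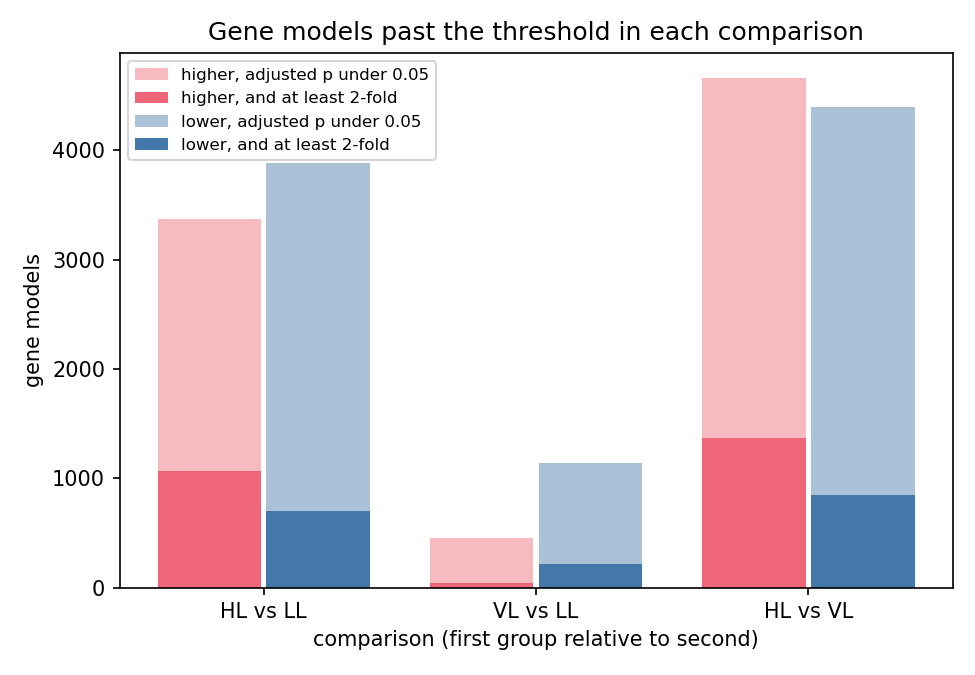
Number of gene models (vertical axis) higher or lower in the first condition than in the second, for each comparison; pale bars pass an adjusted p of 0.05 and solid bars also a fold change of at least 2. HL vs LL gave 3375 higher and 3887 lower, VL vs LL 456 and 1139, and HL vs VL 4657 and 4395.

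In very low against low light, 3 of the 25 models with a symbol passed the limma threshold, each as lower. ACT1 was 2.22-fold lower, at 52.1 ± 22.4 FPKM against 110 ± 15.2 (n = 3 each, limma adjusted p = 0.0455). ARF1 was 1.4-fold lower, at 567 ± 26.1 against 793 ± 41.7 FPKM (n = 3 each, limma adjusted p = 0.0473). SNRNP on scaffold 6 was 1.27-fold lower, at 56.4 ± 1.15 against 72.1 ± 3.19 FPKM (n = 3 each, limma adjusted p = 0.027). Each of these calls was lost in 6 or 7 of the 9 fits that left out 1 library, those of ACT1 and ARF1 also after median-ratio scaling, and that of ACT1 also with the VL and LL libraries alone (adjusted p = 0.051). The highest adjusted p values were 0.133 without LL replicate 3 for ACT1, 0.144 without VL replicate 3 for ARF1 and 0.0928 without LL replicate 1 for SNRNP. RPL3, at 114 ± 37.8 FPKM in VL, and PETC, at 849 ± 140, did not pass the threshold against LL (limma adjusted p = 0.714 and 0.58). FBAII (log2 fold change -0.74), FBAIP (-0.61) and EFL (-0.59) did not pass it either, though their changes were larger than those of ARF1 and SNRNP. With the replicate number as a block these 3 passed it (limma adjusted p = 0.048, 0.0486 and 0.0401), among 7 calls gained. Whether equal numbers pair the VL and LL libraries is open.

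Of the 19601 models, 456 were higher and 1139 lower in VL than in LL, 8.1% of the total, and 41 and 214 of these changed by at least 2-fold. The replicates did not overlap for 7769 models (39.6%, 10% by chance). A model without a symbol on scaffold 9 (991009 to 993230) averaged 19.7 ± 8.03 FPKM in VL, 424 ± 54.4 in LL and 1067 ± 4.62 in HL (n = 3 each). Another on scaffold 100 (284274 to 285796) averaged 1.16 ± 0.536, 25.8 ± 9.57 and 86.8 ± 4.7 FPKM (n = 3 each). On the other side, a model on scaffold 46 (314856 to 319901) stood at 135 ± 37.2 FPKM in VL against 34 ± 7.23 in LL, and one on scaffold 45 (356816 to 358281) at 186 ± 71.1 against 56.4 ± 5.23 (n = 3 each). The counts were unstable: without any 1 VL or LL library they were 58 to 266 higher and 185 to 605 lower, and without HL replicate 1 they were 1102 and 2102. With the replicate number as a block they were 1314 and 2210. Increases made up 28.6% of the calls, against 39.7% after median-ratio scaling and 41.8% after quantile normalization.

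**Figure D3:**
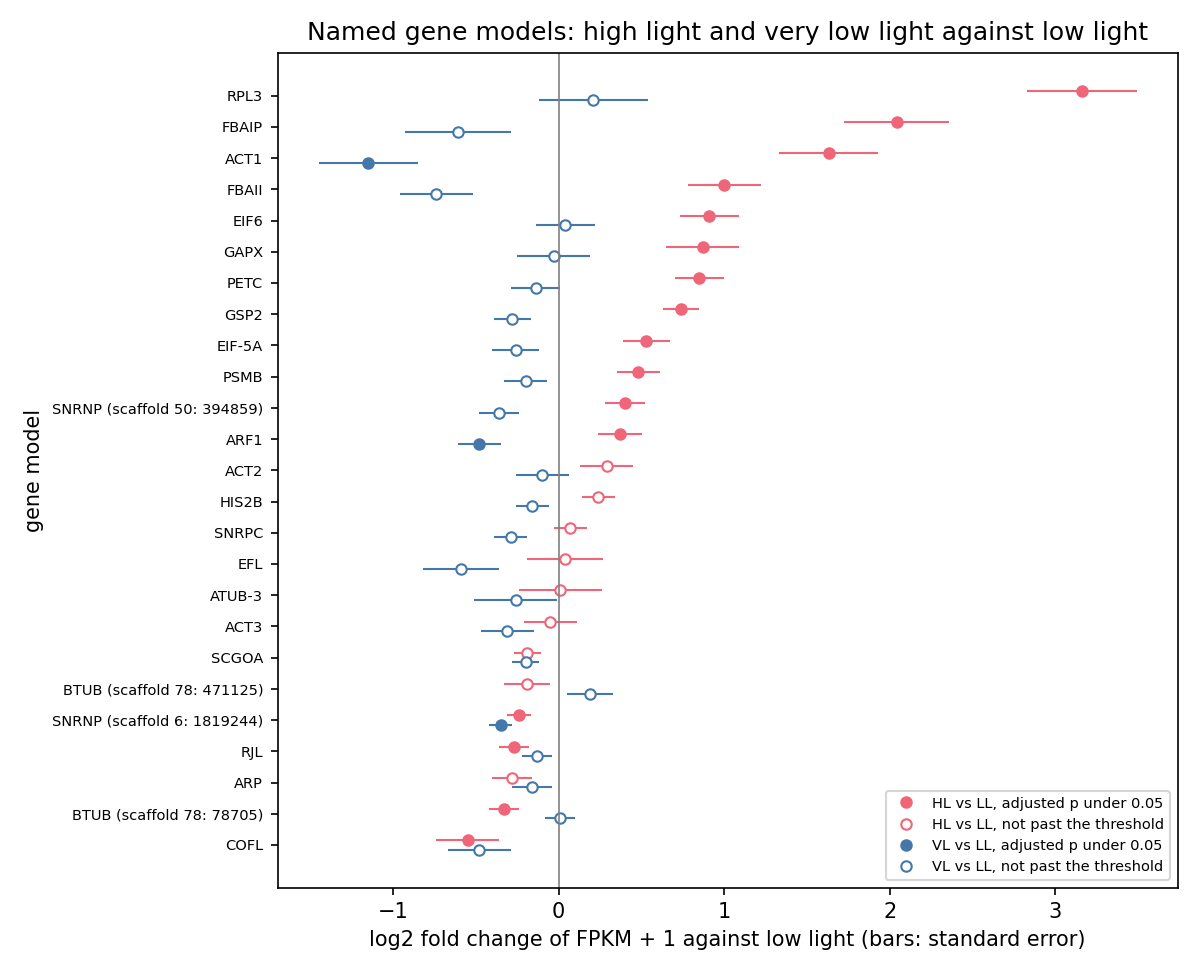
Log2 fold change of FPKM + 1 (horizontal axis) of the 25 gene models with a symbol in HL (red) and VL (blue) against LL; bars are standard errors, n = 3 per condition, and filled points pass an adjusted p of 0.05. In HL, 12 models are past the threshold on the right and 4 on the left, and in VL 0 and 3.

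Between the extremes of light, 14 of the 25 models with a symbol were higher in HL than in VL, 2 were lower and 9 did not pass the threshold. RPL3 was 7.73-fold higher (limma adjusted p = 0.000151), ACT1 6.87-fold (0.000117), FBAIP 6.28-fold (0.000235) and FBAII 3.33-fold (0.000271), with n = 3 per condition. GSP2 was 2.03-fold, PETC 1.99-fold, GAPX 1.87-fold, EIF6 1.83-fold, ARF1 1.8-fold and EIF-5A 1.73-fold higher, the last losing its call under quantile normalization (log2 fold change 0.32, limma adjusted p = 0.0528). HIS2B, histone H2B, was 1.32-fold higher, at 50.1 ± 4.24 FPKM against 37.8 ± 1.18 (n = 3 each, limma adjusted p = 0.00794). Both beta tubulin models were lower, 1.27-fold for the one starting at 78705 on scaffold 78 and 1.3-fold for the one starting at 471125, whose call was lost without any of 7 single libraries (adjusted p of up to 0.146, without VL replicate 2) and with the HL and VL libraries alone (0.0792). Across all models, 4657 were higher and 4395 lower in HL, 46.2% of those tested, with 1366 and 846 at 2-fold or more. The replicates did not overlap for 10865 models (55.4%, 10% by chance). The scaffold 11 model fell from 2713 ± 187 FPKM in VL to 71.1 ± 4.51 in HL (n = 3 each, 37.6-fold). Increases made up 51.4% of the calls, against 37.5% with voom on the implied fragments, where the median model moved by -0.13 against 0.001.

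ACT1 and ARF1 were among 448 models called in opposite directions in HL and VL against LL, and SNRNP on scaffold 6 was among 278 called in the same direction. Higher in HL and lower in VL were 288 models, where independent lists would share 196.1, and lower in HL and higher in VL were 160, against 90.4. Higher in both were 77, against 78.5, and lower in both 201, against 225.9. Simulated unchanged groups against the same LL libraries gave 0 in each class. Where no model changes, almost none passes the threshold, so these zeros are no yardstick for the counts. Over all tested models the covariance of the 2 sets of fold changes was 0, against 0.018 in the simulations (difference -0.018), and the correlation -0.001, against 0.495. The simulated correlation comes from spread alone and the observed one also from changes, so the 2 correlations are not directly comparable. Over the 19570 models quantified in all libraries, the covariance was 0.003, against 0.015 (difference -0.012). These simulations drew the libraries independently. With libraries of equal number correlated as observed, the simulated values were lower, at 0.011 (difference -0.011) and 0.009 (difference -0.006). The 3 LL libraries could not be split. In the simulations, sharing them moved both sets of fold changes the same way, so part of any excess in the same direction may come from them. Opposite calls were above the value for independent lists in all 22 alternatives that fit the libraries here, and same-direction calls in 7. With the replicate number as a block, opposite calls numbered 944, against 786.8, and same-direction calls 921, against 826.7. Without HL replicate 1 the larger excess was in the same direction (925, against 728.3) and little was left in the opposite (708, against 686.9), and without the libraries numbered 1 both were above (680, against 476.9, and 592, against 461.8). Without LL replicate 3, opposite calls numbered 71, against 32.8, and same-direction calls 27, against 33.8.

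In the authors' deposited table, RPL3 has a log2 fold change of 3.27 for HL against LL (q = 0.000302), FBAIP 2.06, ACT1 1.71 and PETC 0.9, all with that q. The authors' deposited table gives ARF1 a q of 0.061, RJL 0.284, BTUB starting at 78705 a q of 0.293 and SNRNP on scaffold 6 a q of 0.382 in that comparison. For VL against LL, the authors' deposited table lists FBAII at -0.73 (q = 0.000302) and EFL, an elongation factor-like GTPase, at -0.55 (q = 0.0187), which limma did not call (adjusted p = 0.0675 and 0.142), and SNRNP on scaffold 6, which limma called, at a q of 0.105. For HL against VL, the authors' deposited table gives q values of 0.0522 for SNRPC and of 0.212 and 0.129 for BTUB starting at 78705 and at 471125, all 3 called by limma, and 0.00542 for EFL, which limma did not call (adjusted p = 0.0502). At q under 0.05, the authors' deposited table holds 4060 loci higher and 3609 lower in HL than in LL, 1847 and 2226 for VL against LL, and 4955 and 4206 for HL against VL. Of the matched models, 6227 were called in both for HL against LL, 1468 for VL against LL and 7840 for HL against VL, and the direction differed for 1, 0 and 1 of them.

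For 6 models the VL libraries, and for 5 of these also the LL libraries, hold failed estimates listed at 0. One of the 5, on scaffold 4 (555946 to 557074), was listed at 0 in the 6 VL and LL libraries and averaged 11457 ± 589 FPKM in HL (n = 3). The model without a value in VL alone, on scaffold 87 (69531 to 72102), averaged 9384 ± 332 FPKM in LL and 2344 ± 383 in HL (n = 3 each). No fold change is given against the conditions in which these models are listed at 0. In all, 34 models had such an estimate in at least 1 library, 28 of them on scaffolds 44 or 66, and none had one in HL. The models with a failed estimate contribute 5 of the higher and 1 of the lower calls in HL against LL, 1 lower call in VL against LL and 7 higher calls in HL against VL. These calls are included in the counts above. Where such a call rests on values listed at 0, its direction is not supported.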

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

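The alternatives were fixed before the data were examined, except the fits without the libraries numbered 1 and with voom, and 2 fits of single models named below, which were chosen after. Counts stayed within 1.5 times the reported ones for HL against LL and HL against VL under every alternative that kept the threshold on adjusted p alone. Requiring a 2-fold change left 1063 higher and 697 lower for HL against LL, 41 and 214 for VL against LL and 1366 and 846 for HL against VL, with 42 opposite and 16 same-direction calls, by its own construction. For VL against LL, fitting the 6 libraries of the 2 groups gave 787 higher, leaving out the libraries numbered 1 gave 729 higher and 680 same-direction calls, and the authors' q gave 1847 higher and 2226 lower; the cause was not tested. Leaving out 1 library at a time gave, for HL against LL, 2466 to 3923 higher and 2599 to 4735 lower, for VL against LL 58 to 1102 and 185 to 2102, for HL against VL 3881 to 4923 and 3367 to 4943, and 71 to 708 opposite and 27 to 925 same-direction calls. Fewer libraries lower the power, but leaving out HL replicate 1 raised all 8 counts. With the replicate number as a block, VL against LL gave 1314 higher and 2210 lower, with 944 opposite and 921 same-direction calls. For HL against LL, where every same-numbered pair correlated over 0.1, the block added the calls of ACT2 and ARP and changed no other call among models with a symbol. These correlations rest on the libraries numbered 1, so whether HL and LL are paired stays open. For the other comparisons 2 of 3 pairs were over 0.1 (lowest 0.03 and 0.09), so the libraries were not treated as paired, and whether they are stays open; there the block added 7 such calls for VL against LL, EFL among them (adjusted p = 0.0401), and 2 for HL against VL, and lost 0. Of the 9 libraries, 8 correlated best with one of their own number, a hint from the data. Among fold changes of models with a symbol that were called in the main fit or the alternative, 1 reversed (uncalled ones that changed sign are not counted): ARF1 in HL against LL had -0.152 under quantile normalization (adjusted p = 0.326; 0.0122 to 0.326 over its alternatives). Of the 16 calls among models with a symbol in HL against LL, 6 held in all 21 fits, of the 3 in VL against LL 0, and of the 16 in HL against VL 13. These fits leave out the 2-fold cut and the authors' q. The fit of the 6 libraries compared and the one without a variance trend were planned for the counts only and were added for these models after the data had been seen; the first ended 8 of the calls and added SNRPC in VL against LL (adjusted p = 0.0474), the second ended 1 (RJL in HL against LL, adjusted p = 0.05). Gene lists could not be recomputed under any alternative, having 1 member at most. With no counts deposited, the part due to depth was not separated from the spread between libraries. In simulated data for HL against LL over 19601 models, 29.9% of changes of 0.5 on the log2 scale were found. That simulation changed few models and gave 136 calls, so its cut-off on unadjusted p was stricter than with the 7262 real calls. The share of small changes missed in the real data is therefore not known.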

Other observations

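The tests and measures below were chosen after the data had been seen, except the counts of other splits. Of 1359 models at least 2-fold higher in HL than in VL, LL lay between the extremes for 1001 (73.7%), and of 846 at least 2-fold lower for 671 (79.3%). With VL at 0 and HL at 1 on the log2(FPKM + 1) scale, the median position of LL was 0.2 for the models higher in HL (quartiles 0.01 and 0.45) and 0.21 for those lower (0.04 and 0.38). Low light itself lies at 0.37 between the extremes on a log scale of light. Models with a failed estimate in any library were left out of these counts.

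The real grouping called 7262 models for HL against LL, 1595 for VL against LL and 9052 for HL against VL, and the highest of the other 9 splits of the same 6 libraries called 2, 14 and 1. In each comparison 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Every other split mixes the conditions, so any difference between them widens its spread and lowers its count. The size of the gap is therefore no measure of chance. For HL against LL, 4 splits part all 3 same-numbered pairs: the real one and 3 that mix the conditions, of which the highest called 2.

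A set of 5 models, on scaffolds 4, 126 and 136, were listed at 0 in all VL and LL libraries and at 2943 to 11457 FPKM on average in HL. Their 30 zeros are all marked as failed estimates, but the models were selected by that mark, so the count of marks is no test of absence in dimmer light. Selected by value alone, 12 models were at 0 in these libraries and at 10 FPKM or more in HL, and 5 of them had failed estimates. The other models show that a 0 can also come with status OK, so this count cannot decide on absence. What the mark means does bear on it, since Cufflinks gives it to a locus with too many fragments. For the loci of the 5 models in VL and LL, that argues against absent transcripts, but it gives no level for a single model. A limit on fragments per locus in the quantification may account for the failed estimates: no quantified model exceeded 0.941 M implied fragments, below the 1 M assumed in the test. The scaffold 87 model reached 0.803 to 0.941 M in LL, where it was quantified, against 0.171 to 0.3 M in HL. Where marked models lie close together, the mark gives no direction for a single one. On scaffolds 44 and 66 it also falls on models near 0 wherever quantified, such as e_gw1.66.111.1 at 0.8 FPKM in VL, 1.3 in LL and 1.6 in HL.

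The libraries numbered 1 deviated from their group means in the same way, with correlations across models of 0.56 for VL with LL, 0.41 for LL with HL and 0.25 for VL with HL. The real numbering had the highest mean correlation of 36 numberings (0.278, the next 0.274), but these libraries prompted the test, so it adds nothing to the observation. Without them, same-numbered libraries correlated at 0.055 for HL with LL, 0.002 for VL with LL and 0.129 for HL with VL (mean 0.062), so whether handling shared by libraries of equal number is the cause stays open, and the labels name no batch. The implied depth of library 1 differed from its group mean by -1.92 M in VL, -0.38 M in LL and 4.65 M in HL, with a pooled SD within groups of 2.81 M. The sides differ, but the VL and LL offsets are within that spread, so sequencing depth stays open too. These depths leave out failed estimates, which fell on 6 models in VL replicate 1 against 34 in each of VL replicates 2 and 3. In LL replicate 1 they fell on 5 models, against 33 and 16 in LL replicates 2 and 3. The VL and LL offsets may therefore be understated in size. No biological explanation was tested.

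Neighbouring models on a scaffold changed together between HL and LL: the correlation of their log2 fold changes across pairs was 0.42 for 661 pairs up to 200 bp apart, 0.145 for 8577 pairs at 200 to 1000 bp and 0.094 for 9989 pairs over 1000 bp apart. The 95 overlapping pairs break this order, at 0.277 (shufflings reached 0.406, permutation p = 0.009, one-sided), and at -0.031 for VL against LL (p = 0.6294). Reads shared by overlapping or close models are argued against as the whole cause by the 0.094 over 1000 bp, since 1000 shufflings of the models reached at most 0.037 (permutation p = 0.001, one-sided, the smallest they can give). For VL against LL the value over 1000 bp was 0.111. Models are not independent replicates, and tandem copies that share reads remain open, as no genome was used here.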
